A study of Mus musculus with 10 samples.

How the data were processed

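RNA from the hearts of 10 mice was compared, 5 A-PDK1KO and 5 control, and each sample was assigned to its group by its genotype label. Reads were paired-end and were inspected with FastQC 0.11.7, per the labels' protocols. Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 1.6.3 and the genome build mm10 are named in the submitters' processing notes. The annotation, the strand setting, the library kit, the sex of the mice and any batch are not given in the sources used here. The labels number the mice 1 to 5 in each group and do not say that a number is shared between groups.

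The deposited values are FPKM (fragments per kilobase of gene, scaled to library size), 1 column per sample for 11790 genes. The lowest of the highest values per gene was 1.00 FPKM, so genes that never reach that level are not analysed here. A column of cluster numbers from 0 to 15 was not used. To find the depth, FPKM values were divided by the value of 1 read, with union exon lengths from GENCODE mouse release 21, whose coordinates are those of the mm10 build. Reads came out whole, within 0.05 of a read, in all samples for 11585 genes, and for 98.5% of single values. The library sizes implied by the value of 1 read were 9249256 to 11384423 counted reads per sample. FPKM are not counts, so the main test used the FPKM values, and a test on the recovered reads was added as an alternative.

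FPKM values were converted to log2(FPKM + 1) here. Genes with a mean of at least 1 FPKM over all 10 samples were tested with limma 3.58.1 in R 4.3.3 (a linear model with an empirical Bayes trend, two-sided), A-PDK1KO minus control, with no covariate. P values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold differences in FPKM are ratios of group means. A total of 50 gene lists were fixed before the data were examined, as were the main test, the filter, the rule for named genes and most other settings tried, and 43 lists had at least 3 tested members. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry, which asks if the genes of a list move on balance in 1 direction, passed 3 lists: oxidative phosphorylation (adjusted p = 0.0105), ribosomal proteins (0.0335) and FoxO targets (0.0447). List means per sample and the level of Pdpk1 were compared by exact two-sided permutation over the 252 splits of 5 against 5, whose smallest p is 0.00794. Such a p is the share of splits of these mice whose difference of group means was, in absolute size, at least the observed one.

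The text names Pdpk1 and the core BCAA genes. It names the 10 largest increases and decreases among called genes whose groups did not overlap, predicted genes left out. From each list it names up to 4 called members of smallest p or, where none was called, members given as values only. The rule allowed values-only members from every list, and the lists from which they are given were chosen after their values were seen. A gene that the rule names is not reported here.

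The limma step was tested on simulated reads for 9674 genes with 5 samples per group. It recovered 54.3% of genes changed 1.5-fold and 94.6% of genes changed 2-fold, and 11 of 150 called genes (7.33%) were unchanged. With no simulated change 0 genes were called. A shift of 0.2 on the log2 scale in all BCAA catabolism genes gave a camera adjusted p of 3.71e-20 and 0 other lists. Those simulated genes vary independently, which the real ones do not.

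Other settings planned were another pseudocount (0.1), no filter or a minimum of 5 FPKM, the TPM scale, median-of-ratios factors, quantile normalization, scaling without mitochondrial and haemoglobin genes, robust variances, sample weights, a replicate block, other thresholds and each sample left out. Added after seeing the data were limma voom on recovered reads, atrial tissue as a covariate, the 6 samples with Myl7 under 10 FPKM, removal of control replicate 4 with A-PDK1KO replicate 2, and removal of a length and GC trend. Samples were checked for duplicates by comparing recovered reads, and no pair within a group matched within sampling noise. Sequence matches were found with BLAST+ 2.17.0 and checks of files were made in Python 3.11.15. Overlapping genes, antisense genes and genes with near-identical copies are uncertain, since the strand setting is not given in the sources used here.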

Results

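RNA was sequenced from the hearts of 10 mice killed in the randomly fed state at 10 to 11 weeks of age. In 5 mice, called A-PDK1KO, 3-phosphoinositide-dependent kinase 1 (PDK1) was deleted in adipocytes, and 5 mice with the floxed gene alone served as controls. PDK1 is encoded by Pdpk1 and phosphorylates AKT downstream of the insulin receptor. It is a different protein from pyruvate dehydrogenase kinase 1, whose gene symbol is Pdk1. The deposited table gave FPKM values for 11790 genes in each heart. The whole reads behind them could be recovered for 98.3% of genes. The value of 1 read implied library sizes of 9249256 to 11384423 counted reads per heart. Mitochondrially encoded transcripts took between 32.7% of the counted reads, in control replicate 4, and 41.5%, in A-PDK1KO replicate 1. The amount of atrial tissue differed between hearts: Myl7, the atrial myosin light chain, stood at 85.9 and 71.4 FPKM in control replicates 2 and 5 and at 35.0 and 47.6 FPKM in A-PDK1KO replicates 3 and 5, and under 1 FPKM in the other 6. The labels do not give the sex. The Y-linked genes Ddx3y (7.07 to 12.35 FPKM) and Eif2s3y (5.83 to 7.60 FPKM) were present in all 10 hearts, so every heart reads as male. A-PDK1KO replicate 2 had 10723 genes at 1 FPKM or more, against 9671 to 10214 in the other hearts. No sample was excluded.

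The study's subject was branched-chain amino acid (BCAA) metabolism in the heart of this mouse, used as a model of diabetic heart disease. Pdpk1 (mm10 chromosome 17, 24073680 to 24150924) was measured first. Its level was 3.77, 3.77, 3.54, 3.54 and 3.14 FPKM in control replicates 1 to 5 and 2.73, 4.04, 3.64, 3.70 and 3.17 FPKM in A-PDK1KO replicates 1 to 5. The difference on the log2(FPKM + 1) scale was -0.04 (exact two-sided permutation test, p = 0.714, n = 5 per group). The deletion was made in adipocytes, so heart RNA does not test it, and values summed over the gene would also count transcripts that lack an exon.

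The genotypes differed in 208 of 9987 genes tested, 121 higher and 87 lower in A-PDK1KO hearts. The natriuretic peptide gene Nppb fell most, from 543 ± 65.1 to 154 ± 54.7 FPKM (mean ± SD, n = 5 per group), which was 3.53-fold lower. Txnip, which encodes a thioredoxin-binding protein that restrains glucose uptake, rose from 48.7 ± 7.11 to 125 ± 55.0 FPKM. It was at 220.6 FPKM in A-PDK1KO replicate 2 and at 88.4 to 120 FPKM in the other A-PDK1KO hearts. Herpud1, a membrane protein of endoplasmic reticulum-associated degradation, rose 2.00-fold, while the endoplasmic reticulum factors Manf and Hspa5 fell. Transcripts for the core steps of BCAA breakdown did not pass the test, and the neutral amino acid transporter gene Slc43a2 rose 2.03-fold.

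Changes were called with limma on log2(FPKM + 1) at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes below are on that scale, which understates the change of low genes. Without adjustment, 1554 genes had a p under 0.05. Of the 208 genes, 51 differed at least 1.5-fold, 37 higher and 14 lower, and the median absolute log2 fold change was 0.43. In 192 of them every A-PDK1KO heart lay on the same side of every control heart. Over all tested genes 495, or 4.96%, were separated in this way, against 0.794% by chance. Which direction prevailed depended on the setting. Higher genes made up 58.2% of the calls, 82.8% (400 calls, 69 of them lower) once mitochondrially encoded and haemoglobin genes were left out of the scaling, and 49.3% (102 higher, 105 lower) with median-of-ratios factors. Their share was 40.9% (61 and 88) without A-PDK1KO replicate 2, 49.6% (61 and 62) without control replicate 1 and 49% (47 and 49) without control replicate 5. The count fell by more than 1.5 times without control replicate 1 (123 genes), control replicate 3 (77), control replicate 5 (96), A-PDK1KO replicate 1 (106), A-PDK1KO replicate 3 (62) or A-PDK1KO replicate 5 (57). It was 62 on the TPM scale, and 4 (1 higher, 3 lower) among the 6 hearts with Myl7 under 10 FPKM, which are only 3 against 3. With all 10 hearts and atrial tissue as a covariate 177 genes passed, 169 of them among the 208.

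Among called genes whose groups did not overlap, the 10 largest increases were those of Cdo1, Txnip, Strit1, Lcn2, Mt2, Herpud1, Fkbp5, mt-Atp6, Slc43a2 and Igsf1. Cdo1, the cysteine dioxygenase of taurine synthesis, rose from 0.805 ± 0.467 to 3.86 ± 1.27 FPKM (log2 fold change 1.42 ± 0.20 SE, limma adjusted p = 0.00956, n = 5 per group). Txnip (chromosome 3, 96557957 to 96561883) had a log2 fold change of 1.26 ± 0.21 (adjusted p = 0.0127). Herpud1 (chromosome 8, 94386438 to 94395377) had one of 0.98 ± 0.12 (adjusted p = 0.00497) and ranged from 69.1 to 88.4 FPKM in controls and from 118 to 194 FPKM in A-PDK1KO hearts. Strit1, which encodes the calcium pump activator DWORF, rose by a log2 fold change of 1.17, Lcn2 (lipocalin 2) by 1.01, Mt2 (a metallothionein) by 0.98, Fkbp5 (a glucocorticoid-induced co-chaperone) by 0.94, mt-Atp6 (a subunit of ATP synthase) by 0.83 and Igsf1 by 0.79. Lcn2 and Cdo1 lay near the floor in controls. Lcn2 was at 0.688 ± 0.225 and 2.45 ± 0.918 FPKM from 10 to 101 reads per heart, and Cdo1 had 6 to 90 reads per heart. With 1 heart left out, the calls of Cdo1, Txnip, Herpud1, Lcn2, Slc43a2 and Igsf1 held in all 10 fits. Strit1 was lost in 7 fits and Mt2 in 7 (adjusted p up to 0.0711 and 0.0859, both without control replicate 3), Fkbp5 in 3 (up to 0.0606 without control replicate 3) and mt-Atp6 in 9 (up to 0.117 without A-PDK1KO replicate 5). The genes mt-Atp6 and mt-Atp8 overlap, so the value of mt-Atp6 is uncertain. Of 15 mitochondrially encoded transcripts tested mt-Atp6 was the 1 called. Adjusted over their list alone 1 was higher and 2 were lower, and the list did not pass (camera adjusted p = 0.256).

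By the same rule the 10 largest decreases were those of Nppb, Scd4, Scgb1c1, Bex1, Manf, Frmd5, Tfpi, P4ha1, Ankrd1 and Serpinh1. Nppb (chromosome 4, 147985788 to 147987205) had a log2 fold change of -1.89 ± 0.21 SE (limma adjusted p = 0.00429, n = 5 per group). Scd4, a stearoyl-CoA desaturase of the heart, fell from 5.09 ± 1.92 to 1.72 ± 0.581 FPKM (log2 fold change -1.13, adjusted p = 0.0175), and Manf fell from 14.8 ± 2.89 to 8.22 ± 0.424 FPKM (log2 fold change -0.76, adjusted p = 0.00956). Tfpi, the tissue factor pathway inhibitor, had a log2 fold change of -0.68. The collagen-modifying genes P4ha1 and Serpinh1, a prolyl hydroxylase and the collagen chaperone HSP47, both had log2 fold changes of -0.65. So did Ankrd1, the stress-responsive cardiac ankyrin repeat protein, at 325 ± 20 and 211 ± 48.1 FPKM. Scgb1c1, Bex1 and Frmd5 had log2 fold changes of -0.86, -0.81 and -0.72. Bex1 lay near the floor, at 1.64 ± 0.451 and 0.510 ± 0.240 FPKM from 2 to 28 reads per heart. It passed the filter, and was called, in 8 of the 10 fits that left out 1 heart. With 1 heart left out, Ankrd1 was lost in 7 of 10 fits (adjusted p up to 0.0839 without A-PDK1KO replicate 5), Serpinh1 in 4 (up to 0.0749 without A-PDK1KO replicate 5) and Scd4 in 1 (0.0513 without A-PDK1KO replicate 3).

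**Figure D1:**
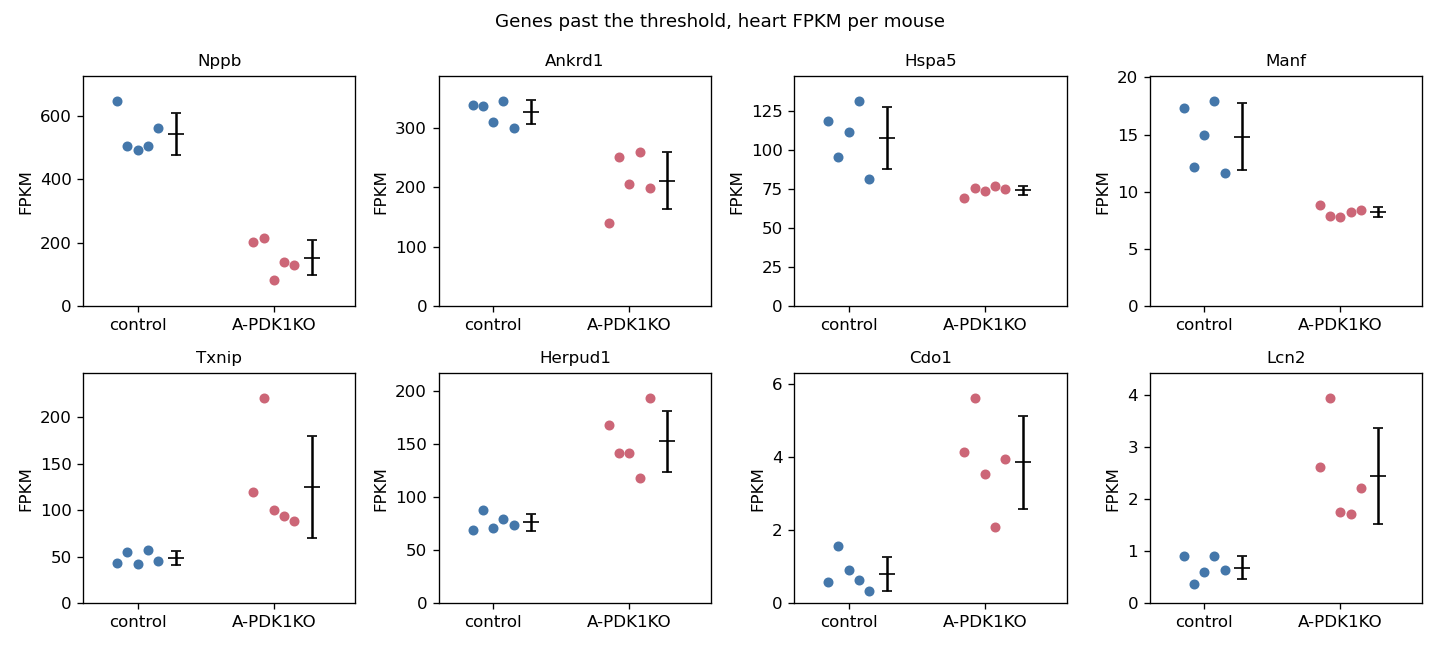
FPKM of 8 genes past the threshold in each heart (points), with mean and SD beside them, for 5 control and 5 A-PDK1KO mice; each vertical axis starts at 0. Nppb lay between 491 and 648 FPKM in controls and between 81.6 and 215 FPKM in A-PDK1KO hearts.

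Branched-chain amino acid breakdown was the subject of the study. All 7 genes of its core steps were expressed, and none passed the threshold. Bckdha, the E1 alpha subunit of the branched-chain ketoacid dehydrogenase (chromosome 7, 25629946 to 25658981), stood at 143 ± 16.1 FPKM in controls and 169 ± 14.6 FPKM in A-PDK1KO hearts (log2 fold change 0.25 ± 0.08 SE, limma adjusted p = 0.173, n = 5 per group). It was the 1 core gene whose unadjusted limma p was under 0.05, and none passed with limma voom on the recovered reads. Bcat2, the mitochondrial transaminase, was at 19.1 ± 1.83 and 21.1 ± 2.14 FPKM. The kinase Bckdk was at 23.0 ± 1.49 and 23.5 ± 1.28 FPKM, and the phosphatase Ppm1k at 10.4 ± 1.5 and 11.8 ± 2.31 FPKM. Bckdhb, Dbt and Dld, the other subunits of the complex, had log2 fold changes of 0.03, 0.13 and -0.08. In the wider list of 26 tested BCAA catabolism genes 0 were called, also when adjusted over the list alone. At an unadjusted p under 0.05, 3 were higher and 2 lower, and voom called 1 as higher. Acat1 was at 104 ± 9.08 and 129 ± 16.9 FPKM and Hsd17b10 at 112 ± 3.56 and 98.2 ± 6.03 FPKM (adjusted p = 0.121 and 0.108). As a group the 26 genes had a median log2 fold change of 0.05, with 17 above 0 (camera adjusted p = 0.493, 0.967 with an estimated correlation). The 7 core genes had a median of 0.13, with 6 above 0 (camera adjusted p = 0.348, 0.941 with an estimated correlation). List means per heart gave exact permutation p of 0.444 and 0.198 before adjustment. By camera at the preset correlation, both lists passed as higher after quantile normalization (adjusted p = 0.0408 and 0.0376) and under no other setting tried. The preset correlation was 0.01, while those estimated in the main setting were 0.58 and 0.52. Of 9 amino acid transporter genes tested, Slc43a2 (chromosome 11, 75531694 to 75577575) rose from 3.02 ± 0.476 to 6.11 ± 0.988 FPKM (log2 fold change 0.82 ± 0.11, limma adjusted p = 0.00956). The other 8 were not called, and the transporter list did not pass (camera adjusted p = 0.232).

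**Figure D2:**
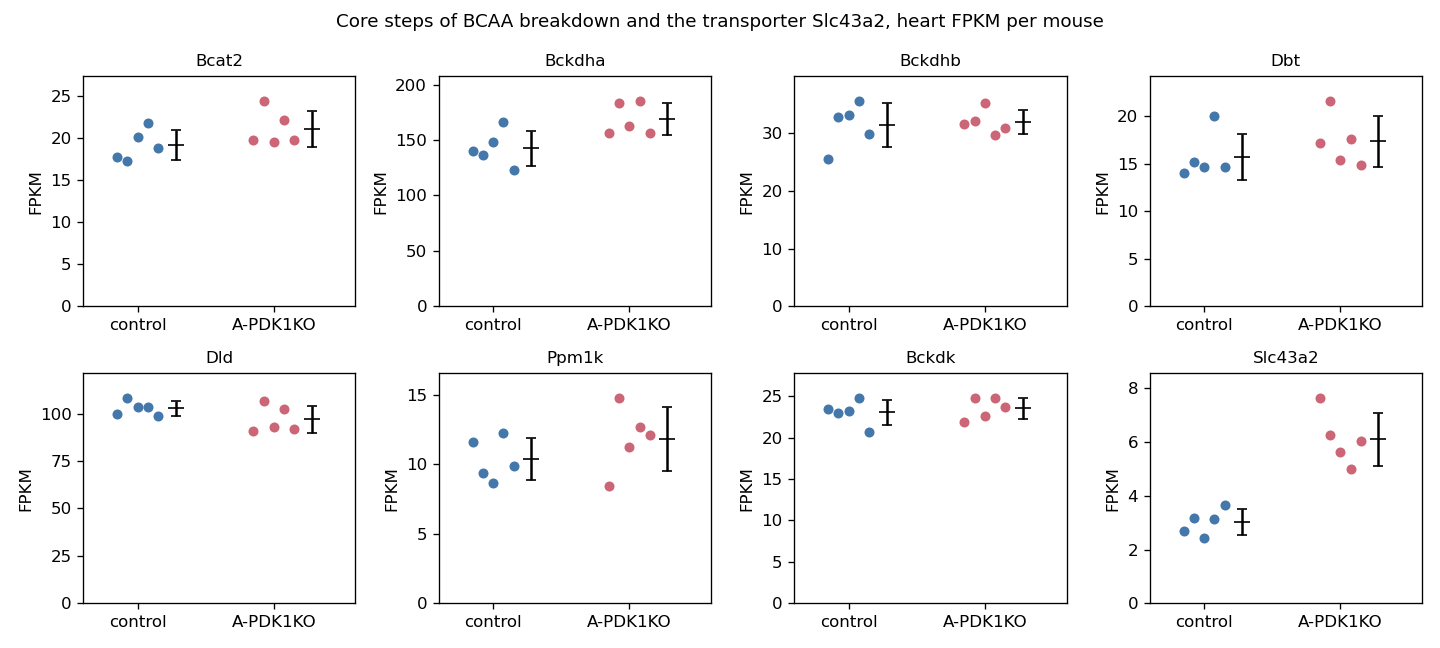
FPKM of the 7 core genes of BCAA breakdown and of the transporter gene Slc43a2 in each heart (points), with mean and SD beside them; each vertical axis starts at 0. The groups overlapped in the 7 core genes and were separated in Slc43a2.

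Gene lists fixed in advance were tested with camera at a preset inter-gene correlation of 0.01. Of 43 lists with at least 3 tested members 11 passed, 4 as higher and 7 as lower. With a correlation estimated from the data 0 passed, and the lowest adjusted p was 0.171. In 19 of 100 splits of the 10 hearts into 5 and 5, the real one included, the preset correlation passed at least 11 lists. The mean of each list per heart was compared by an exact two-sided permutation test. In 8 lists p was under 0.05 before adjustment, and in 0 after it (lowest adjusted p = 0.0853). PPAR-alpha targets, FoxO targets, oxidative phosphorylation and cytosolic ribosomal proteins each separated all 5 A-PDK1KO hearts from all 5 controls, at the smallest p that the 252 splits can give, 0.00794. For PPAR-alpha targets A-PDK1KO replicate 2 had a mean of 5.94, against 5.48 to 5.64 in the other 4 A-PDK1KO hearts, and without it the difference between groups was 0.16 in place of 0.24.

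The fatty acid uptake and oxidation list passed as higher by camera at the preset correlation. Of 26 genes tested, 5 rose, or 11 when adjusted over the list alone, 0 fell, and 25 had a log2 fold change above 0 (median 0.18, camera adjusted p = 2.24e-08, adjusted p = 0.533 with an estimated correlation). Ech1 rose from 556 ± 32.6 to 684 ± 44.4 FPKM, and Hadh, a dehydrogenase of beta-oxidation, from 120 ± 7.22 to 146 ± 7.76 FPKM (limma adjusted p = 0.0325 and 0.0331). Slc25a20 carries acyl-carnitines into the mitochondrial matrix, where Cpt2 turns them back into acyl-CoA. Cpt2 and Slc25a20 had log2 fold changes of 0.29 and 0.25. PPAR-alpha targets passed as well, with Slc25a20 the 1 called of 19, or 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.000262, adjusted p = 0.533 with an estimated correlation). That list shares members with the fatty acid list, Slc25a20 among them, so its result is not independent of it. Lipid storage and lipolysis genes had 1 of 19 called, or 5 adjusted over the list alone (median 0.07, camera adjusted p = 0.0192, adjusted p = 0.759 with an estimated correlation). The called gene was Abhd5, the activator of adipose triglyceride lipase, at 7.37 ± 0.228 and 9.50 ± 0.449 FPKM (log2 fold change 0.33). With 1 heart left out, Ech1 and Hadh were each lost in 8 of 10 fits (adjusted p up to 0.0851 and 0.0837, both without A-PDK1KO replicate 3), Cpt2 and Slc25a20 in 9 (up to 0.109 without A-PDK1KO replicate 5 and 0.107 without A-PDK1KO replicate 3) and Abhd5 in 4 (up to 0.0686 without A-PDK1KO replicate 5). The lipid storage list was lost without control replicate 1 (adjusted p = 0.0571) and without A-PDK1KO replicate 4 (0.0512), with voom on recovered reads (0.15, median 0.03) and with a replicate block (0.0618). Its median was 0.11 without control replicate 4 and 0.12 without A-PDK1KO replicate 1.

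The list of FoxO transcription factor targets and muscle atrophy genes also passed as higher by that test. Of 25 genes tested, 6 rose, or 8 when adjusted over the list alone, which also gave 1 lower (median log2 fold change 0.19, camera adjusted p = 0.000296, adjusted p = 0.486 with an estimated correlation). Besides Txnip these included the autophagy genes Gabarapl1 and Ulk1 and the ubiquitin ligase gene Fbxo21. Gabarapl1 rose from 88.0 ± 14.9 to 150 ± 21.8 FPKM (log2 fold change 0.77, limma adjusted p = 0.0127), and Ulk1 and Fbxo21 had log2 fold changes of 0.37 and 0.42. Fbxo32, the atrophy ubiquitin ligase atrogin-1, and Ccng2, a cyclin, were the other 2, with log2 fold changes of 0.64 and 0.54. Both fall outside the rule for named genes and were chosen after their values were seen. Among 23 autophagy and lysosome genes 4 rose, Gabarapl1, Ulk1, Wipi1 (0.37) and the protease gene Ctsl (0.37), or 6 adjusted over the list alone with 1 lower, and the list itself did not pass (camera adjusted p = 0.0897). It did pass as higher with a filter of 5 FPKM (0.0248), the TPM scale (0.045), quantile normalization (0.0059), scaling without mitochondrial and haemoglobin genes (0.0228), atrial tissue as a covariate (0.0376) or without A-PDK1KO replicate 2 (0.0417). Among 21 insulin signalling components Akt1 was the 1 called, from 30.8 ± 1.04 to 23.1 ± 1.56 FPKM (log2 fold change -0.40, limma adjusted p = 0.00956). The insulin signalling list did not pass (camera adjusted p = 0.895). With 1 heart left out, Gabarapl1 and Akt1 held in all 10 fits. Ulk1 and Ccng2 were each lost in 7 (adjusted p up to 0.0839 without A-PDK1KO replicate 5), Fbxo32 in 8 (up to 0.0966 without control replicate 3), Ctsl in 8 (up to 0.083 without control replicate 3), Fbxo21 in 5 (up to 0.0793 without A-PDK1KO replicate 5) and Wipi1 in 3 (up to 0.0539 without control replicate 5).

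The list of the unfolded protein response in the endoplasmic reticulum passed as lower. Of its 21 genes tested, Manf, Hspa5 and Pdia4 fell, or 10 genes when adjusted over the list alone, and Herpud1 rose (median log2 fold change -0.22, camera adjusted p = 6.94e-06, adjusted p = 0.486 with an estimated correlation). Hspa5, which encodes the chaperone BiP, fell from 108 ± 19.7 to 74.2 ± 2.89 FPKM (log2 fold change -0.51, limma adjusted p = 0.0329), and Pdia4 had a log2 fold change of -0.42. Of 16 heat shock genes Hspb1 was called, from 327 ± 51.6 to 227 ± 31.7 FPKM, or 5 adjusted over the list alone, all lower (median -0.22, camera adjusted p = 3.39e-05, adjusted p = 0.486 with an estimated correlation). The transcription factors Atf4 (20.1 ± 3.38 and 16.3 ± 4.59 FPKM) and Cebpb (39.5 ± 7.63 and 31.8 ± 4.56 FPKM) were not called. With 1 heart left out, Hspa5 was lost in 8 of 10 fits (adjusted p up to 0.0859 without control replicate 3), Hspb1 in 8 (up to 0.0839 without A-PDK1KO replicate 5) and Pdia4 in 5 (up to 0.0686 without control replicate 3), and Manf and Herpud1 in none.

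Cytosolic ribosomal protein and oxidative phosphorylation lists passed as lower, by an amount that depended on the scaling. Of 38 ribosomal protein genes 3 fell, or 11 adjusted over the list alone, and 36 had a log2 fold change below 0 (median -0.15, camera adjusted p = 1.03e-14, adjusted p = 0.414 with an estimated correlation). Rpsa fell from 124 ± 4.07 to 100.2 ± 4.73 FPKM (limma adjusted p = 0.0133), and Rps15 and Rps2 had log2 fold changes of -0.24 and -0.25. These families have many processed pseudogenes that can share reads, so single members are uncertain. Of 74 nuclear-encoded oxidative phosphorylation genes 1 fell, Ndufs6, also 1 adjusted over the list alone, and 67 had a log2 fold change below 0 (median -0.10, camera adjusted p = 6.32e-11, adjusted p = 0.171 with an estimated correlation). Ndufs6, a subunit of complex I, had a log2 fold change of -0.23 (limma adjusted p = 0.0384). With scaling that left out mitochondrial and haemoglobin genes both lists passed, with medians of -0.08 for ribosomal proteins and -0.03 for oxidative phosphorylation (camera adjusted p = 1.95e-11 and 2.76e-05), while the median of all genes moved from 0.02 to 0.08. After quantile normalization the medians were -0.09 and -0.02, and oxidative phosphorylation did not pass (adjusted p = 1.16e-05 and 0.129). Leaving out 1 heart at a time lost Ndufs6 in all 10 fits (adjusted p up to 0.103 without A-PDK1KO replicate 3), Rps2 in 8 and Rps15 in 6 (up to 0.0839 without A-PDK1KO replicate 5 and 0.0851 without A-PDK1KO replicate 3) and Rpsa in 1 (0.0522 without A-PDK1KO replicate 5).

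**Figure D3:**
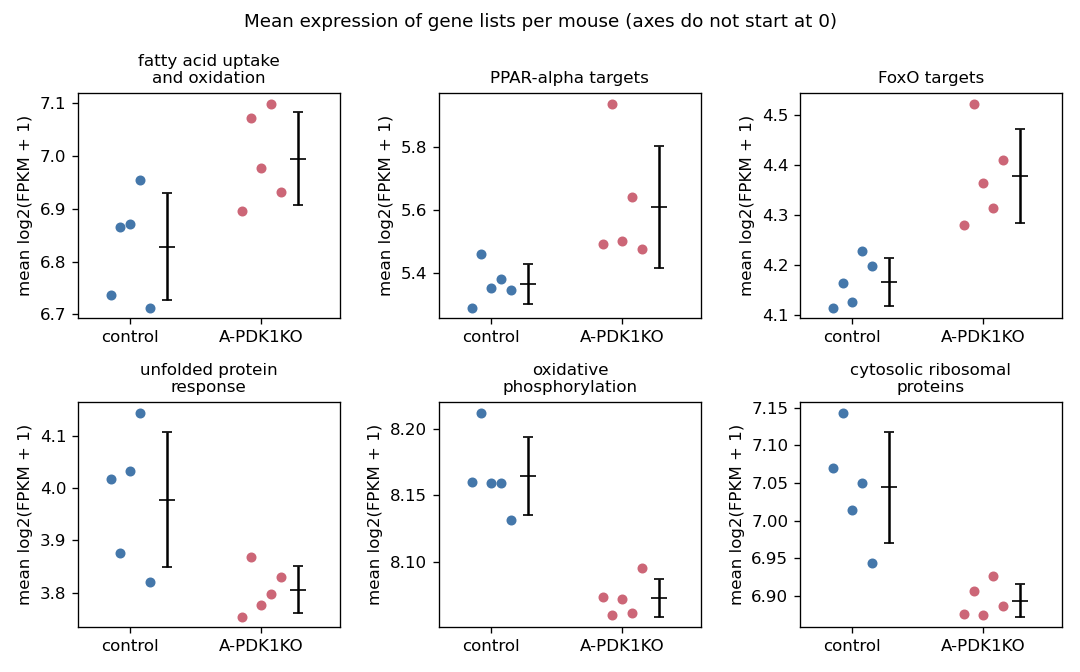
Mean log2(FPKM + 1) of 6 gene lists in each heart (points), with mean and SD over 5 hearts per group beside them; the axes do not start at 0. The groups did not overlap for PPAR-alpha targets, FoxO targets, oxidative phosphorylation and ribosomal proteins, and overlapped for the other 2.

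Among genes of cardiac stress and contraction, Nppb and Ankrd1 were the 2 called of 13 fetal program genes, both lower, or 3 adjusted over the list alone (median log2 fold change -0.22, camera adjusted p = 0.0457, adjusted p = 0.486 with an estimated correlation). The mean of the list per heart was 6.17 and 6.04 in control replicates 2 and 5 and 5.46 and 5.77 in A-PDK1KO replicates 3 and 5, the 4 hearts with Myl7 over 10 FPKM, and 4.98 to 5.30 in the other 6. With atrial tissue as a covariate the list passed (adjusted p = 0.00702). The atrial marker list, which shares members with it, had a median of -0.25 over 13 tested genes and did not pass (camera adjusted p = 0.143). It passed as lower without mitochondrial and haemoglobin genes in the scaling (0.0434), with atrial tissue as a covariate (0.0141) and without control replicate 3 (0.0498), A-PDK1KO replicate 3 (0.038) or A-PDK1KO replicate 5 (0.0302). Its median was 0.03 without control replicate 2, 0.01 without control replicate 5, 0.02 without A-PDK1KO replicate 1, -0.02 without A-PDK1KO replicate 2 and -0.06 without A-PDK1KO replicate 4, and in none of these 5 fits did it pass. Nppa, the atrial natriuretic peptide gene, was at 375 ± 117 and 206 ± 54.3 FPKM and was not called (limma adjusted p = 0.0908). The list lost its call without control replicate 2 (adjusted p = 0.134), control replicate 5 (0.164), A-PDK1KO replicate 2 (0.169) or A-PDK1KO replicate 4 (0.0624), where its median was 0.00, -0.03, -0.05 and 0.00, and it had a median of 0.03 without A-PDK1KO replicate 1, where it passed (0.0394). It also lost its call with a pseudocount of 0.1 (0.0541), a filter of 5 FPKM (0.208), median-of-ratios factors (0.129), quantile normalization (0.265, median -0.08), sample weights (0.0921, median -0.11), a replicate block (0.0618), the length and GC trend removed (0.0659), without control replicate 4 and A-PDK1KO replicate 2 together (0.0604) and in the 6 hearts with Myl7 under 10 FPKM (0.0569, median -0.05). Of 20 sarcomere genes Myoz2 fell, from 343 ± 16.6 to 271 ± 11.5 FPKM, or 3 adjusted over the list alone. The list passed as lower (median -0.05, camera adjusted p = 0.00276, adjusted p = 0.759 with an estimated correlation). It did not pass after quantile normalization (adjusted p = 0.376), with a filter of 5 FPKM (0.0738), without control replicate 4 and A-PDK1KO replicate 2 together (0.106) or in the 6 hearts with Myl7 under 10 FPKM (0.069). Leaving out 1 heart gave medians from -0.11, without control replicate 1, to -0.01, without control replicate 4. Of 27 calcium handling and ion channel genes Hcn2 and Kcnip2 fell, by log2 fold changes of -0.59 and -0.52, or 3 adjusted over the list alone. The calcium handling list did not pass (camera adjusted p = 0.165). In the leave-one-out fits Kcnip2 was lost in 2 of 10 fits, without A-PDK1KO replicate 5 and without A-PDK1KO replicate 3 (adjusted p up to 0.0537, the latter), and Hcn2 and Myoz2 in none.

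Other called genes fell in lists that did not pass as a whole. In glycogen metabolism, the synthase gene Gys1 was higher (log2 fold change 0.37), and the primer gene Gyg (-0.28), Ugp2 (-0.32) and Stbd1 (-0.50) were lower among 14 tested. The ketone dehydrogenase gene Bdh1 was lower (-0.88) and the pyruvate dehydrogenase phosphatase gene Pdp1 higher (0.42). In oxidative stress defence Hmox1, haem oxygenase 1, was higher (1.19) and Gpx1, glutathione peroxidase 1, lower (-0.39). In the glucocorticoid response list Fkbp5, Lcn2, Mt2 and Mt1 (0.62) were higher among 16 tested. That list had a median of -0.06 and a mean of 0.15, and camera gave an upward direction (adjusted p = 0.348). Ccn1 (0.58) was higher in the immediate early list. In fits that left out 1 heart, Gpx1 held in all 10. Stbd1 was lost in 10 (limma adjusted p up to 0.112 without control replicate 5), Ugp2 in 9 (up to 0.1 without control replicate 3) and Bdh1, Hmox1 and Ccn1 in 8 each (up to 0.0969, 0.103 and 0.0921, all without control replicate 3). Gys1 was lost in 7, Gyg in 5, Mt1 in 4 and Pdp1 in 3 (up to 0.0839, 0.0749, 0.0666 and 0.0696, all without A-PDK1KO replicate 5).

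No single gene was called in the interferon, fibrosis, endothelial, adipocyte and glycolysis lists. Of 13 interferon response genes 0 were called by limma, also adjusted over the list alone, and by voom, and 4 were lower at an unadjusted p under 0.05. The list passed as lower with 12 log2 fold changes below 0 (median -0.24, camera adjusted p = 0.000262, adjusted p = 0.533 with an estimated correlation). Bst2 was at 16.5 ± 1.72 and 12.1 ± 2.60 FPKM and Ifit1 at 1.97 ± 0.628 and 1.24 ± 0.225 FPKM (limma adjusted p = 0.107 and 0.197). Of 33 fibrosis and matrix genes 0 were called, also adjusted over the list alone, while 3 were higher at an unadjusted p under 0.05 and voom called 1 as higher. Thbs2 was at 2.14 ± 0.164 and 2.94 ± 0.343 FPKM and Eln at 3.56 ± 0.736 and 4.94 ± 0.963 FPKM (adjusted p = 0.0658 and 0.188). Of 18 endothelial markers 0 were called, with 1 higher when adjusted over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05 and 1 higher with voom. Cldn5 was at 11.6 ± 3.16 and 20.4 ± 6.24 FPKM (adjusted p = 0.0765) and Plvap at 4.76 ± 0.954 and 3.35 ± 0.797 FPKM. Of 4 adipocyte markers past the filter 0 were called by limma or voom, and 0 had an unadjusted p under 0.05. Pparg was at 3.98 ± 0.571 and 3.31 ± 0.394 FPKM and Thrsp at 9.79 ± 1.77 and 8.51 ± 1.67 FPKM. Of 19 glycolysis genes 0 were called by limma or voom and 2 were lower at an unadjusted p under 0.05, with Pgk1 at 126 ± 10.1 and 113 ± 4.65 FPKM and Pgam1 at 29.0 ± 4.23 and 24.1 ± 2.67 FPKM. The glycolysis list did not pass (camera adjusted p = 0.158), but passed as lower without control replicate 1 (0.000567).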

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

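Tests of 182 groups of 5 hearts for a single heart far from the rest (Dixon's criterion) marked 12, where chance marks about 1 in 20, or 9.1. The neighbour test of Gm7049 and the atrial and cardiomyocyte tests were chosen after the results were seen, as were the resampling of list members and the tests of scaling and of quantile normalization.

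In control replicate 4, Dbt was at 20.1 FPKM against 14.0 to 15.1 in the other controls, and mt-Atp6 at 604 FPKM against 1140 to 1420. In control replicate 1, Bdh1 was at 8.45 FPKM against 13.7 to 15.1, Hsd17b10 at 106 FPKM against 112 to 115, and the summed haemoglobin transcripts at 1380 FPKM against 27.5 to 245. In control replicate 5, Wipi1 was at 21.5 FPKM against 23.2 to 23.7, Ech1 at 498 FPKM against 566 to 575, and Plvap at 3.10 FPKM against 4.84 to 5.40. Ctsl was at 36.4 FPKM in control replicate 2 against 30 to 31.3, and Hspb1 at 419 FPKM in control replicate 3 against 294 to 313. Igsf1 was at 4.05 FPKM in A-PDK1KO replicate 1 against 4.80 to 5.00, and Rpsa at 108 FPKM in A-PDK1KO replicate 4 against 96.2 to 99.5.

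The 208 changed genes were set against other splits of the 10 hearts into 5 and 5. Of 100 splits, drawn from 126 possible ones, 1, the real one, gave as many, and the highest of the others gave 3. Chance division of the hearts is so an unlikely source of the gene count. The test cannot tell the genotype from a litter or batch difference that follows it. For the 11 gene lists passed by camera at the preset correlation chance division stays open. There 19 of 100 splits, the real one included, gave as many lists, and the highest of the others gave 14.

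Gm7049, a processed pseudogene of Me1 (malic enzyme 1) on chromosome 13 (62813076 to 62814787), had the smallest p of all genes; it falls outside the rule for named genes and was chosen after its values were seen. It stood at 0.214 ± 0.138 FPKM in controls and 3.87 ± 0.210 FPKM in A-PDK1KO hearts (n = 5 per group, 2 to 80 reads per heart). Reads from a risen parent transcript are argued against, since Me1, 98.4% identical over 1716 bases, had a log2 fold change of -0.03. Reads from Gm48795, annotated on the other strand over 819 of the same bases, are not excluded. Gm7329, a shorter match on chromosome 1 (98.1% over 210 bases), was at 0 FPKM in the controls and 0.827 ± 0.775 FPKM in A-PDK1KO hearts, from at most 4 reads per heart. A strain block carried with the transgene could not be decided: 1 of 14 tested genes within 3 Mb, Ctsl, passed the threshold, and a block need not alter its neighbours' expression. For that reason the count that would exclude a block was changed from fewer than 50% of the neighbours to 0 of them after the 1 had been seen. A sequence difference at this locus or at Me1, or an effect of the genotype on it, stays open and was not tested.

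Lower ribosomal protein and oxidative phosphorylation transcripts are short and abundant, so technical sources were tested first. A length and GC trend was removed from each heart. The ribosomal list then kept 78% of its median log2 fold change (95% range over resampled members 68.9 to 97.5). Ranges of this kind resample genes and hold the hearts fixed, so they leave out variation between hearts. They also treat genes as independent, while the estimated correlation among ribosomal protein genes was 0.27. For these hearts alone, the 78% argues against that trend as the whole cause. Oxidative phosphorylation kept 67% (46.8 to 78.9), so for that list the trend and the genotype cannot be told apart, as the range reaches below the bound set in advance. Without control replicate 4 and A-PDK1KO replicate 2, whose mitochondrial share was lowest, the lists kept 106% and 110%, which argues against those hearts as the source. With mitochondrial and haemoglobin genes left out of the scaling, the ribosomal list kept 56% (51.8 to 61.6) and oxidative phosphorylation 30% (6.58 to 40.2). This moved most genes about alike, the median of all genes going from 0.02 to 0.08, and left the lists 0.17 and 0.11 below it as before, so it decides nothing on that source. After quantile normalization they kept 60% (53.6 to 68.9) and 26% (9.26 to 42.9), and their distance below the median of all genes shrank to 0.09 and 0.02. That step removes a difference between hearts in the spread of values over all genes. For ribosomal proteins such a difference is argued against as the whole cause in these hearts alone, as the range leaves out variation between hearts. It stays open for oxidative phosphorylation, whose median was -0.13 with median-of-ratios factors and with voom. RNA quality and an effect of the genotype stay open and untested.

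The lower Nppb could come from unequal atrial tissue, since 4 hearts held it. Among the 6 hearts with Myl7 under 10 FPKM, Nppb kept 83% of its log2 fold change (-1.57) and the groups did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows), which argues against that source. Nppa differed by -0.46 in those 6 hearts, where its groups overlapped, and by -1.42 in the other 4, so atrial tissue stays open for Nppa. A lower share of cardiomyocytes is argued against by the sarcomere list, whose median log2 fold change was -0.05 against -1.89 for Nppb. An effect of the genotype on Nppb is a hypothesis found and tested on the same hearts.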

How the results depend on the processing

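The tests on recovered reads, on atrial tissue, on length and GC, and without control replicate 4 and A-PDK1KO replicate 2 were chosen after seeing the data; the others were planned. Against 208 changed genes (121 higher, 87 lower), the TPM scale gave 62 (41 and 21), scaling without mitochondrial and haemoglobin genes 400 (69 lower, 82.8% higher against 58.2%), sample weights 412 (219 and 193) and voom on recovered reads 350 (186 and 164). An adjusted p under 0.1 gave 369, a fold of at least 1.5 gave 51, and 495 genes were at the smallest exact permutation p. The cause of the shifts between scalings was not tested. Leaving out 1 heart gave 57 to 150 genes, 29 to 94 higher and 24 to 88 lower, with fewer hearts in each fit: 123, 77 and 96 genes without control replicates 1, 3 and 5, and 106, 62 and 57 without A-PDK1KO replicates 1, 3 and 5. Without control replicate 4 and A-PDK1KO replicate 2 there were 141 (76 higher). The 6 hearts with Myl7 under 10 FPKM, 3 against 3, gave 4 (1 higher, 3 lower). With atrial tissue as a covariate there were 177, of which 169 were among the 208. Of the called genes that the rule names, Nppb and Manf passed in all 25 alternatives. Gene lists passed by camera numbered 9 to 13 against 11. By camera at the preset correlation, the BCAA catabolism and core lists passed only after quantile normalization (adjusted p = 0.0408 and 0.0376). In the other settings their adjusted p was 0.156 to 0.815 and 0.167 to 0.497, and the cause was not tested. Lists with an unadjusted score p under 0.05 numbered 8, against 4 on the TPM scale, 14 with median-of-ratios factors, 14 with quantile normalization, 13 without mitochondrial and haemoglobin genes, 13 with voom and 0 in the 6 hearts, where 3 against 3 cannot pass. Leaving out 1 heart gave 6 to 11. Hearts that share a replicate number gave no sign of pairing over all genes. Correlations of their deviations were -0.05, -0.12, 0.05, 0.09 and 0.08, and no control correlated best with its own number. A shared litter or batch is not excluded by this. With a replicate block 153 genes passed (92 higher, 61 lower), 124 of them among the 208, 9 lists passed, and 0 list scores did, as the smallest p within blocks is 0.0625. Robust variances and sample weights give no list scores, and Pdpk1 lies under the filter of 5 FPKM. In no setting did a called gene that the rule names, or camera's direction for a called list, reverse. Other called genes were not checked for this. The median of the fetal program did change sign, from -0.22 to 0.03 without A-PDK1KO replicate 1 and to 0.00 without control replicate 2 or A-PDK1KO replicate 4. That of the sarcomere list went from -0.05 to 0.01 without mitochondrial and haemoglobin genes, where the median of all genes rose as much, from 0.02 to 0.08. Pdpk1 and uncalled genes near 0 also changed sign in some settings. At this depth the self-test recovered 54.3% of 1.5-fold changes, so changes of that size can be missed. Smaller changes of single genes were not simulated.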

Other observations

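Genes outside the rule for named genes and among the smallest p were chosen after their values were seen. Fbxo31, a ubiquitin ligase component, rose from 32.2 ± 3.42 to 50.4 ± 2.48 FPKM (log2 fold change 0.63, limma adjusted p = 0.00429, n = 5 per group). The linker histone genes H1f0 and H1f2 rose from 42.6 ± 3.67 to 62.7 ± 5.56 FPKM and from 135 ± 14.9 to 207 ± 21.7 FPKM (log2 fold changes 0.55 and 0.62, both adjusted p = 0.00956). Spock2, a matrix proteoglycan, rose by a log2 fold change of 0.76, Tacc2 by 0.52 and Tfdp2, a partner of E2F factors, by 0.47. The alpha-tubulin gene Tuba1b fell from 29.4 ± 1.80 to 20.7 ± 1.73 FPKM (log2 fold change -0.48, adjusted p = 0.00956). In these 7 genes every A-PDK1KO heart lay on the same side of every control heart, as in 192 of all 208 called genes. All 7 calls held in the 10 fits that left out 1 heart. The genes were chosen by their p in the same hearts, so neither adds independent evidence.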
